A study of Mus musculus with 3 samples.

How the data were processed

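Mouse bone marrow cells were profiled by droplet single-cell RNA sequencing in 3 libraries, 1 for each Fabp4 genotype (wild type, heterozygous knockout and homozygous knockout). Each library pooled cells of 2 mice, and no file assigned a cell to a mouse. Groups were taken from the genotype stated for each sample, because the title letters do not spell out the genotypes.

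The deposited matrices hold whole-number UMI counts per gene and barcode, not normalized. They were made with Cell Ranger version 8.0.1, per the file headers. Cell Ranger with STAR and the build mm10 are named per the submitters' processing notes, which give no annotation release. The 10x Genomics Chromium 3' v3 kit was used, per the labels' protocols. Of the 33696 genes, 1684 had Ensembl IDs that the GENCODE M21 annotation of GRCm38 used here does not hold, so the build and annotation behind the counts remain uncertain and only the position of Fabp4 is printed from that annotation. The deposited barcodes had already been filtered, since the lowest total was 500 UMIs.

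The choices in this paragraph and the next were made before the data were examined, unless stated otherwise. Cells were kept with at least 500 UMIs, at least 200 genes and a mitochondrial share of UMIs under 10%. Doublets were called with the Scrublet method in scanpy per library. Its automatic threshold marked 0.036% of the wild-type cells and 0% of the homozygous ones. In those libraries the top-scoring cells were removed instead, at 0.8% per 1000 barcodes, following a rule set for calls under 0.5% or over 20%. Doublet removal took 423 wild-type, 184 heterozygous and 280 homozygous cells. Kept cells numbered 5181, 7773 and 4038, which was 54.9%, 72.5% and 49.8% of the deposited barcodes.

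Counts were scaled to 10000 UMIs per cell and log-transformed. The 3 libraries were clustered together on 2000 variable genes, 30 principal components and 15 neighbours by the Leiden method at resolution 1.0, without batch integration. Xist, Tsix, Y-linked genes, antigen receptor segments and Fabp4 were left out of the variable genes. The resulting 17 clusters were named from 20 fixed marker lists, and several clusters could share a name. A name needed at least 3 raised markers, and the thresholds of that scoring rule were set after the data were seen. Of the clusters, 1 remained unnamed, and its share is given per library. Tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9.

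UMIs were summed per library and class and expressed as CPM, the UMIs of a gene in each 1000000 UMIs of that sum. Intervals are 95% exact Poisson (Garwood) for a level, exact binomial (Clopper-Pearson) for a share, Newcombe for a difference of shares, log-normal for a ratio of shares and exact conditional for a ratio of levels. These intervals cover counting error only. With 1 library per genotype no spread between animals can be estimated, so no p-value is given and no genes are counted as different. A level of 0 was set against a floor of 3 counts per library. Within-class ratios were computed in the 5 classes with at least 100 kept cells in each library. Both knockout comparisons use the same wild-type library, so any likeness between them may come in part from that library.

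For each of 28 fixed gene lists, the median log2 CPM ratio was taken over members with at least 20 UMIs in the 2 libraries compared. It was placed among 10000 random lists of the same size matched on mean expression, and this percentile describes these libraries only. The interval of a list median comes from 1000 Poisson draws. Genes named by rank were ordered by the bound of the ratio interval nearest to 0, given at least 50 UMIs in 1 of the libraries compared and a class CPM of at least 0.2 of the gene's highest class CPM in that library. The rule names 10 genes per direction in stem and progenitor-like cells for each knockout, and 5 per direction in the other classes for the homozygous library. It leaves out haemoglobin, mitochondrial, ribosomal, sex-linked, antigen receptor and unnamed gene models. Members of the fixed lists were also named as examples, chosen after their values were seen. Shares of cells with a marker UMI were also computed after thinning each cell to 1000 UMIs.

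The code was tested on simulated counts in which 200 genes had known ratios. For the homozygous against wild-type comparison of stem and progenitor-like cells, run on 10371 genes, the intervals covered 98% of the true ratios at log2 1, 92% at log2 2 and 95.7% of the unshifted genes. The simulated counts came from the Poisson model that the intervals assume. The test therefore checks the code and not whether the intervals hold for real cells.

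Of the alternatives, 18 were fixed in advance. They were other cell filters (no filter, or at least 1000 UMIs with a mitochondrial share under 5%), doublets kept, Leiden resolutions of 0.5 and 2.0, 15 principal components, assignment of each cell by its marker score and thinning to 2000 UMIs. For ratios and lists they were median-of-ratios size factors, equal weight per cell, a minimum of 100 UMIs, list means and totals without haemoglobin, S100a8, S100a9 and mitochondrial genes. After the data were seen, 5 were added, namely a mitochondrial share under 25% for Fabp4 and for class shares, the latter also without the clusters unnamed there, kept cells of at least 5000 UMIs only, and shares without the unnamed cluster.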

Results

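Bone marrow cells of Fabp4 wild-type, heterozygous knockout and homozygous knockout mice were profiled by 3' single-cell RNA sequencing, with 1 library per genotype and 2 mice pooled in each. Fabp4 encodes the adipocyte fatty acid-binding protein, a cytosolic carrier of fatty acids. The series asks whether leukaemia stem cells depend on Fabp4 when normal blood stem cells do not. The sample labels do not state whether the marrow carried leukaemia. The wild-type library held 9432 barcodes and 77173735 UMIs, the heterozygous library 10718 barcodes and 78426908 UMIs, and the homozygous library 8115 barcodes and 54160590 UMIs. Median UMIs per kept cell were 9761, 7545 and 8740.5 in that order. There are no replicate libraries, so each difference below compares these libraries and not the genotypes, and each interval is a 95% counting interval.

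Fabp4 RNA was scarce in wild-type marrow and lowest in the homozygous library. Kept cells held 47 Fabp4 UMIs in the wild-type library (0.789 CPM, interval 0.579 to 1.05), 35 in the heterozygous library (0.503 CPM, 0.350 to 0.699) and 3 in the homozygous library (0.0726 CPM, 0.0150 to 0.212). The log2 ratio to wild type was -3.44 (-5.77 to -1.81) for the homozygous library and -0.65 (-1.32 to 0.01) for the heterozygous one, so the latter difference was within counting error in kept cells. Over all barcodes the heterozygous ratio was -0.79 (-1.37 to -0.22), an interval that excluded 0 but treats UMIs of the same cell as independent. The shares of barcodes with a Fabp4 UMI, 0.467% in the wild-type and 0.289% in the heterozygous library, had overlapping intervals. Monocyte-like cells held 39 of the Fabp4 UMIs in the wild-type, 17 in the heterozygous and 0 in the homozygous library, which puts the wild-type level at least 12.5-fold above the homozygous floor of 0.146 CPM per library. In stem and progenitor-like cells, 1 Fabp4 UMI was found in the wild-type library and 0 in both knockouts. A Fabp4 UMI was present in 1.24% of wild-type monocyte-like cells (median 9853 UMIs per cell) and in 0.0903% of stem and progenitor-like cells (median 11639 UMIs). After thinning to 1000 UMIs, 5 wild-type, 2 heterozygous and 1 homozygous cells still had one.

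Fabp4 (ENSMUSG00000062515) lies on the minus strand of chromosome 3, from 10204088 to 10208576 in the GENCODE M21 annotation of GRCm38. Transcript Fabp4-201 has 4 exons, and exon 4, the last, spans 10204088 to 10204570. The labels do not say which part of Fabp4 was deleted, and 3' tags from outside the deleted part would check nothing. The monocyte-like cluster numbered 7 held 31 of the 47 wild-type Fabp4 UMIs and few homozygous cells. At the wild-type Fabp4 level of each cluster, the homozygous cells would have held 19.1 UMIs where 3 were counted (0.619 to 8.77), and the heterozygous cells 21.2 where 35 were counted (24.4 to 48.7). Much of the homozygous 19.1 rests on 1 wild-type UMI in the unnamed cluster, and in the named clusters the value was 9.98 where 2 were counted (0.242 to 7.22). The values at wild-type levels carry no interval and rest on few wild-type UMIs, such as 6 in 4 cells of cluster 6. Whether the homozygous level was lower beyond cluster make-up therefore stays unsettled.

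Stem and progenitor-like cells, named from a marker list that includes Cd34, Kit, Meis1 and Mecom, made up 21.4% of kept wild-type cells (1107 of 5181, interval 20.3% to 22.5%), 6.27% of heterozygous cells (487 of 7773, 5.74% to 6.83%) and 4.36% of homozygous cells (176 of 4038, 3.75% to 5.03%). The share was 17.0 percentage points higher in the wild-type than in the homozygous library (difference homozygous minus wild type -17.0, -18.3 to -15.7), and the heterozygous minus wild-type difference was -15.1 (-16.4 to -13.9). These cells were 1 cluster, whose leading gene was the eosinophil granule gene Prg3 and whose eosinophil score of 1.90 exceeded its stem and progenitor score of 1.08. Its name rests on 9 raised stem and progenitor markers. Cd34 was higher there than in any other class, at 64.5, 60.2 and 69.2 CPM in wild-type, heterozygous and homozygous cells. Meis1 and Mecom did not set it apart in each library. Homozygous Meis1 stood at 821 CPM there and at 861 CPM in granulocyte-monocyte progenitor-like cells. Heterozygous Mecom stood at 962 CPM in that cluster and at 1218 CPM in conventional dendritic cell-like cells. Angpt1, a leading gene of that cluster, encodes a ligand of the Tie2 receptor. Summed over cells of every class, its RNA stood at 112 CPM in wild-type, 54.0 in heterozygous and 27.7 in homozygous kept cells. Over all barcodes it stood at 105, 53.3 and 25.6 CPM. As Angpt1 was picked from that cluster, these values are not independent of the cluster's share. Cd34, a surface marker of progenitors, stood at 26.6, 10.3 and 10.2 CPM in kept cells and at 23.4, 10.1 and 9.60 CPM over all barcodes. Kit, the stem cell factor receptor, was nearer to equal at 28.6, 22.6 and 22.5 CPM in kept cells and 32.4, 24.6 and 26.4 CPM over all barcodes. The mitochondrial filter, which can set these shares, removed 40.6% of wild-type, 25.8% of heterozygous and 46.8% of homozygous barcodes, and at a limit of 25% the shares were 18.8%, 5.64% and 2.51%. Clusters unnamed at that limit held 22.2%, 17.8% and 48.7% of the cells, and among the remaining named cells the shares were 24.2%, 6.86% and 4.88%. Within both knockout libraries the share also differed between cells with Y-linked RNA only and cells with Xist only, at 5.21% against 12.8% in the heterozygous and 21.6% against 3.57% in the homozygous library. These sets depend on Xist detection, and Xist levels were lower in neutrophil-like than in stem and progenitor-like cells.

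Neutrophil-lineage cells dominated the heterozygous library. Immature neutrophil-like cells, which make secondary granule proteins such as lactoferrin (Ltf), were 25.9% of heterozygous cells (24.9% to 26.9%) against 9.26% in the wild-type (8.49% to 10.1%) and 5.75% in the homozygous library (5.05% to 6.51%). Mature neutrophil-like cells were 18.6% against 2.26% and 4.11%. Granulocyte-monocyte progenitor-like cells were 27.8% of wild-type, 25.7% of heterozygous and 27.0% of homozygous cells. The split into these classes depended on the clustering. At resolution 0.5 granulocyte-monocyte progenitor-like cells were 6.43%, 0.219% and 0.619%, immature neutrophil-like cells 21.8%, 25.9% and 26.6% and mature ones 10.4% of wild-type and 41.2% of heterozygous cells, and by marker score granulocyte-monocyte progenitor-like cells were 21.1%, 10.7% and 22.0%. The 3 granulocytic classes together were 39.3%, 70.2% and 36.8%, and the heterozygous minus wild-type difference was 30.9 points (29.2 to 32.6). The homozygous minus wild-type difference of -2.47 points (-4.46 to -0.47) turned positive under several alternatives, for example 2.86 without the unnamed cluster. In the heterozygous library, 77.7% of cells with Y-linked RNA only were granulocytic against 40.2% of those with Xist only, 63.1% of the 810 with both and 74.9% of the 1414 with neither.

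Monocyte-like cells, marked by Csf1r, Ccr2 and Ly6c2, were 35.8% of wild-type (34.5% to 37.2%), 17.6% of heterozygous (16.8% to 18.5%) and 43.0% of homozygous cells (41.4% to 44.5%). With the mitochondrial limit at 25% they were 24.5% of wild-type and 24.8% of homozygous cells, and 31.5% and 48.3% of the cells in named clusters there. Conventional dendritic cell-like cells were 1.85%, 4.77% and 1.68%. T cell-like cells, among them natural killer cells, were 0.463%, 0.232% and 0.570%. Megakaryocyte-like cells numbered 1, 8 and 0, and 0 of 4038 cells has an upper bound of 0.0913%. At resolution 1.0 with doublets removed, no cluster met the marker rule for B cells, plasma cells, erythroid cells, basophils or stromal cells. A plasma cell cluster of 55 cells was named with doublets kept, and a mesenchymal stromal cluster of 7 cells at resolution 2.0. At that resolution an eosinophil cluster of 389 cells (234 wild-type, 97 heterozygous and 58 homozygous) was also named, with raised Prg2, Siglecf and Prg3. A cluster in which no class reached 3 raised markers with a score of 0.5 was left unnamed. It held 60 wild-type (1.16%), 63 heterozygous (0.811%) and 549 homozygous cells (13.6%), with median UMIs of 1310, 1672 and 1350. Its median mitochondrial share was 7.51%, 7.42% and 7.68% in that order, against 2.87%, 1.95% and 2.53% in the other kept cells.

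**Figure D1:**
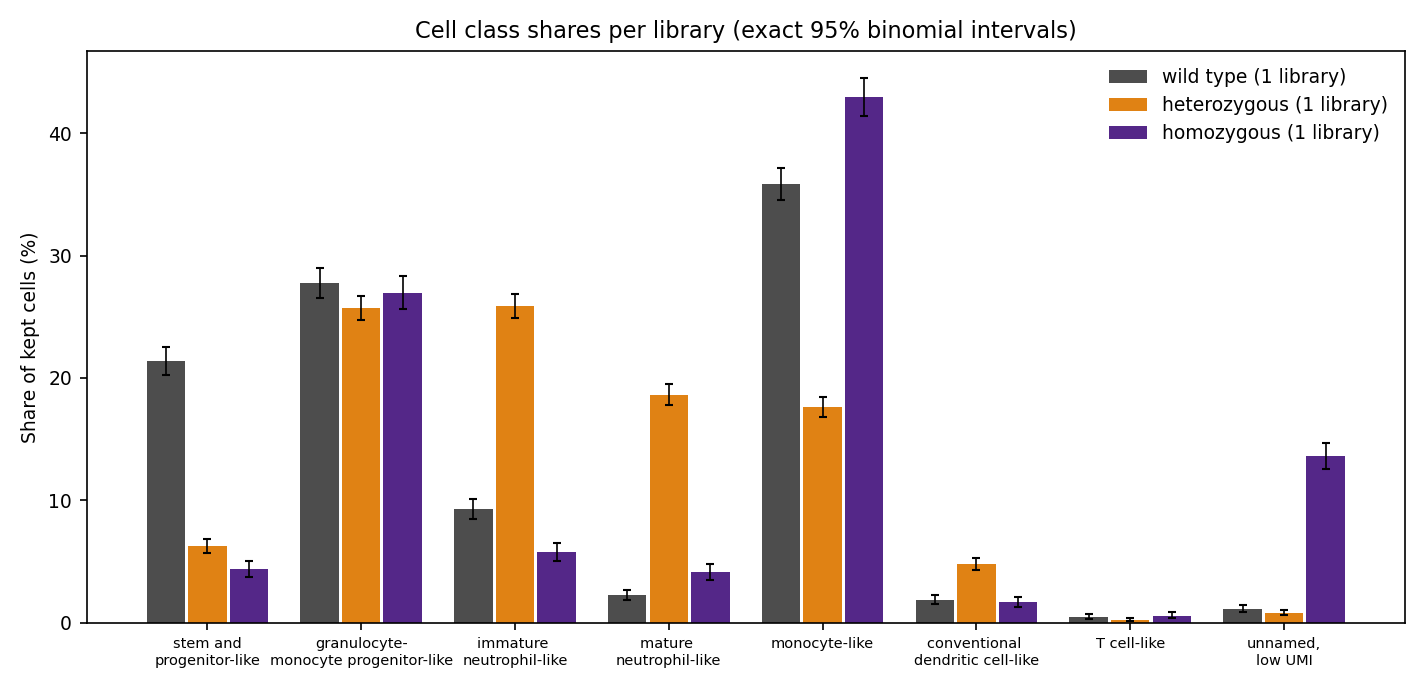
Share of kept cells (percent, bars) per cell class in the wild-type, heterozygous and homozygous libraries, with exact 95% binomial intervals as error bars and 1 library per genotype. Stem and progenitor-like cells were 21.4%, 6.27% and 4.36%, and the heterozygous bars stand highest for immature (25.9%) and mature (18.6%) neutrophil-like cells.

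Homozygous against wild type in stem and progenitor-like cells, interferon response genes were higher throughout. Of 33 measured members, which act in antiviral defence, 33 were higher and 0 lower in the homozygous library, with a median log2 ratio of 0.90 (0.74 to 1.06) above 100% of random lists. Isg15, a ubiquitin-like modifier, stood at 8.12 CPM in wild-type and 27.5 in homozygous cells (log2 1.76, 1.30 to 2.21), and Bst2, which tethers budding viruses, at 55.8 and 129 CPM (log2 1.21, 1.01 to 1.40). The neutrophil primary granule list was also higher in the homozygous library, in 8 of 10 members (median 0.76, 0.69 to 0.86), led by the serine proteases Ctsg (log2 1.90, 1.82 to 1.98) and Elane (log2 1.21, 1.17 to 1.24) and by myeloperoxidase, Mpo (log2 1.47, 1.40 to 1.54). S phase genes were higher in 35 of 42 members (median 0.31, 0.24 to 0.40), among them the replicative helicase subunit Mcm5 (log2 0.66, 0.41 to 0.89). Oxidative phosphorylation genes were slightly higher in 27 of 30 members (median 0.18, 0.13 to 0.21, percentile 99.9), and the 13 mitochondrially encoded genes had a median of -0.11 (4 higher, 9 lower). The summed RNA of 4 Y-linked genes also differed in these cells, at 7.84 CPM in the wild-type and 77.0 CPM in the homozygous library.

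Lipid genes, the nearest to the function of Fabp4, had no common direction in the homozygous stem and progenitor-like cells. Fatty acid binding and uptake genes were split, with 6 of 12 higher and 6 lower (median 0.10, -0.15 to 0.31, percentile 64.6). Within that list, Fabp5, which encodes a related fatty acid-binding protein, stood at 40.4 CPM in wild-type and 92.6 in homozygous cells (interval of the log2 ratio 0.97 to 1.42). Fatty acid and triglyceride synthesis genes were mostly lower, in 11 of 18 members (median -0.20, -0.34 to 0.01, percentile 0.93), among them ATP citrate lyase, Acly (log2 -1.06, -1.33 to -0.81), and fatty acid synthase, Fasn (log2 -0.98, -1.47 to -0.52). Fatty acid oxidation genes were higher in 15 of 21 members (median 0.22, 0.08 to 0.30, percentile 96.4). Cholesterol synthesis genes had a median of 0.23 (-0.01 to 0.32, percentile 91.7) and PPAR gamma targets -0.07 (-0.32 to 0.18, percentile 18.1).

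Stem cell and leukaemia genes were mixed in the same cells. The haematopoietic stem cell list had 11 of 20 members higher and 9 lower (median 0.16, -0.15 to 0.18, percentile 87.3), and the leukaemia stem cell and Hox-Meis program list 14 of 25 higher and 11 lower (median 0.01, -0.10 to 0.10, percentile 42.0). Across the alternatives the haematopoietic stem cell median ranged from -0.14 to 0.16, so its direction was not settled. Several transcription factor genes of these lists were lower in the homozygous library. Pbx3 stood at 1842 CPM in wild-type and 772 in homozygous cells (log2 -1.26, -1.32 to -1.19), Meis1 at 1461 and 821 CPM (log2 -0.83, -0.90 to -0.77) and Mecom at 1371 and 941 CPM (log2 -0.54, -0.61 to -0.48). Hoxa9, the homeobox gene that Meis1 and Pbx3 proteins partner, was close to equal at 203 and 227 CPM (log2 0.17, 0.03 to 0.30). Homozygous stem and progenitor-like cells with Xist only held Pbx3 at 399 CPM, and the 29 such cells with Y-linked RNA only held it at 2882 CPM.

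The other lists in this comparison follow. Unfolded protein and heat shock response genes were higher in 16 of 18 members (median 0.28, percentile 99.99), NF-kB and inflammatory cytokine genes in 16 of 22 (0.36, percentile 100) and dissociation and immediate early genes in 13 of 17 (0.23, percentile 99.8). G2 and M phase genes had a median of 0.17 (32 of 50 higher, percentile 95.3), ribosomal protein genes 0.12 (28 of 31 higher, percentile 96.9) and MYC targets 0.10 (19 of 27 higher, percentile 85.3). Secondary and tertiary granule genes had a median of -0.17 (5 of 15 higher, percentile 6.32) and STAT3 and PI3K-AKT feedback genes -0.09 (percentile 11.7). Medians lay between -0.03 and 0.05 for glycolysis (0.04), DNA methylation machinery (0.05), MHC class II presentation (0.04), haemoglobin and erythroid RNA (0.03), hypoxia response (0.00), p53 targets and cell death (-0.01) and ferroptosis and antioxidant genes (-0.03). The 6 sex-linked genes had a median of 3.08, with 4 higher and 2 lower.

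Ordered by the interval bound nearest to 0, the genes highest in homozygous over wild-type stem and progenitor-like cells were led by Cpa3, the mast cell carboxypeptidase (0.503 and 60.6 CPM, log2 6.91, 5.83 to 8.25), Ctla2a, a cysteine protease inhibitor (log2 6.18, 4.74 to 8.11), the junction scaffold Magi1 (log2 5.68, 4.55 to 7.05) and Auts2 (log2 2.41, 2.21 to 2.60). With doublets kept, the log2 ratio was 1.08 for Ctla2a, 9.11 for Cpa3 and 1.22 for Maml2. The next were Igfbp4 (log2 2.69), Cdk5rap1 (2.54), Dynlt5 (2.30), Ctsg, Maml2 (2.12) and Kcnn4 (1.90). The genes lowest in homozygous cells were led by Raet1d, which encodes a stress ligand of the natural killer receptor NKG2D. Raet1d had 0 UMIs in homozygous and heterozygous stem and progenitor-like cells, and its wild-type level of 9.35 CPM was at least 7.60-fold and at least 17.2-fold above their floors of 3 counts per library. The related ligand gene Raet1e stood at 62.0 and 11.9 CPM (log2 -2.38, -2.97 to -1.85). Ptprt (log2 -4.26), Dach1 (2066 and 599 CPM, log2 -1.79, -1.86 to -1.71), Ush1c (-4.19), P2ry14 (-1.92), Fbxl18 (-2.87), Tln2 (-2.47), Glb1l (-2.13) and Sptan1 (-1.63) completed the 10. With equal weight per cell, the ratio was -1.60 for Fbxl18 and -1.24 for Glb1l.

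**Figure D2:**
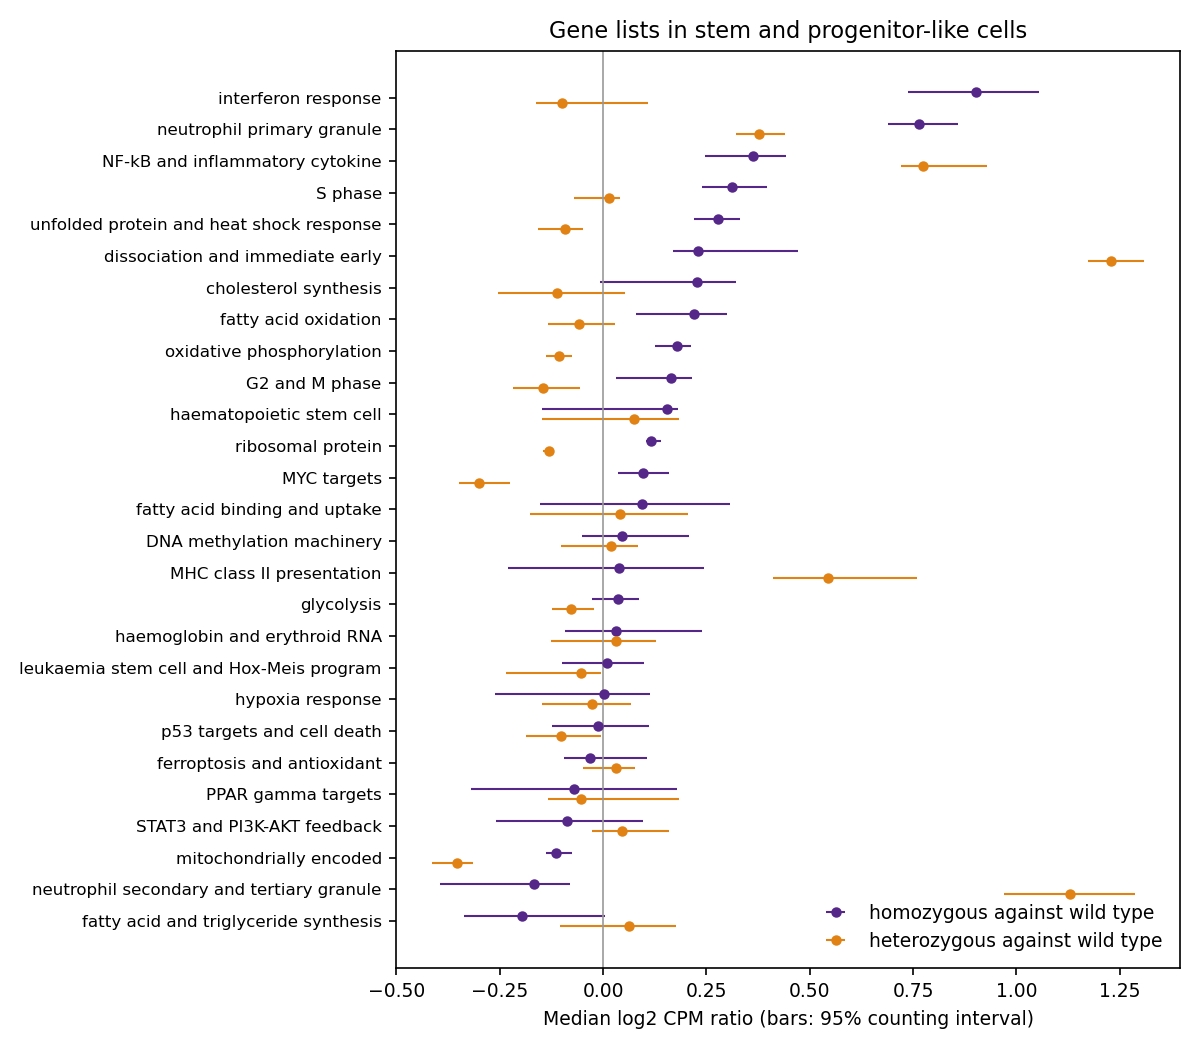
Median log2 CPM ratio to wild type (x axis) of 27 gene lists in stem and progenitor-like cells, as points for the homozygous and the heterozygous library with 95% counting intervals as bars, the sex-linked list being left out for its range. The homozygous interferon response median (0.90) and the heterozygous dissociation and immediate early (1.23) and secondary granule (1.13) medians stand farthest to the right.

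In the more mature classes, interferon response genes were again higher in the homozygous library. Their median log2 ratio to wild type was 0.77 in granulocyte-monocyte progenitor-like cells (29 of 34 higher), 1.09 in immature neutrophil-like cells (25 of 27), 1.55 in mature neutrophil-like cells (23 of 23) and 1.23 in monocyte-like cells (37 of 37), each above 100% of random lists. In monocyte-like cells, Ifit3, an antiviral gene of the IFIT family, stood at 3.66 CPM in wild-type and 40.6 CPM in homozygous cells (log2 3.47, 3.14 to 3.83). Cell cycle genes were higher too, with medians of 0.63 for G2 and M phase (50 of 51 higher) and 0.18 for S phase in granulocyte-monocyte progenitor-like cells, and of 0.55 for S phase (40 of 42) and 0.40 for G2 and M phase (49 of 51) in monocyte-like cells. The cycling cluster numbered 8 held 25.4% of wild-type and 46.5% of homozygous granulocyte-monocyte progenitor-like cells. Wild-type monocyte-like cells lay mostly in clusters 3 and 7, homozygous ones in clusters 11, 14 and 6, and cluster 11 was led by interferon-induced genes such as Ifi204.

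Homozygous monocyte-like cells had lower levels of several gene lists. Fatty acid binding and uptake genes had a median of -0.32 (5 of 14 higher, percentile 0.03), with lipoprotein lipase, Lpl, at 23.9 CPM in wild-type and 10.8 in homozygous cells (log2 -1.15, -1.38 to -0.92), against a higher Fabp5 (28.7 and 48.7 CPM, log2 0.76, 0.62 to 0.91). PPAR gamma targets had a median of -0.31, glycolysis -0.23, hypoxia response -0.23, NF-kB and inflammatory cytokine genes -0.22 and STAT3 and PI3K-AKT feedback genes -0.34, where the cytokine signalling inhibitor Socs3 stood at 48.3 and 15.7 CPM (log2 -1.62, -1.81 to -1.44). The haematopoietic stem cell list had a median of -0.71 (4 of 20 higher). These values come from different mixes of clusters in the libraries, as given above.

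Pbx3 was lower in the homozygous library in every granulocytic class, and not in these classes alone. Monocyte-like cells held it at 999 CPM in the wild-type, 948 in the heterozygous and 215 in the homozygous library. In granulocyte-monocyte progenitor-like cells it stood at 1106 CPM in the wild-type, 1028 in the heterozygous and 98.2 in the homozygous library (log2 homozygous to wild type -3.49, -3.57 to -3.42), in immature neutrophil-like cells the log2 ratio was -2.51 (-2.67 to -2.36) and in mature ones -2.59 (-2.89 to -2.30). Outside T cells, Pbx3 stood at 131 CPM in homozygous cells with Xist only and at 1945 CPM in the 118 cells with Y-linked RNA only. Hoxa9 was higher in homozygous granulocyte-monocyte progenitor-like cells (255 and 431 CPM, log2 0.76, 0.70 to 0.81). The Mpo-rich cluster numbered 9 held 23.6% of wild-type and 3.12% of homozygous cells of that class. Among its ranked genes, the X-linked Xlr family genes Xlr4a (log2 6.13, 4.89 to 7.76) and Xlr3b (5.73), Gnasas1 (6.36), Eps8l1 (4.49) and Capn11 (3.36) were highest, and Elavl2, a neuronal RNA-binding protein gene (log2 -7.62, -12.93 to -5.13), Xlr (-5.82), C79798 (-3.83) and Zc3h12c (-3.61) were lowest beside Pbx3. Elavl2 was at least 116-fold above the floor of the heterozygous library, which had 0 UMIs. The Xlr3b ratio was 3.23 with doublets kept, and the Zc3h12c ratio -4.87 with the strict cell filter.

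In immature neutrophil-like cells the ranked genes highest in the homozygous library were Rtp4 (log2 2.66, 1.97 to 3.39), Syne3 (2.25), Isg15 (1.70), Slfn5 (1.84) and the death receptor gene Fas (1.76), and the lowest were Raet1d (at least 19.5-fold higher in wild type), Pbx3, Sox4 (-3.15), Zc3h12c (-2.48) and C79798 (-2.35). With the strict cell filter, these ratios were 1.24 for Slfn5, -1.77 for Sox4, -3.31 for Pbx3 and -3.21 for C79798. In mature neutrophil-like cells Isg15 (log2 3.72, 2.77 to 4.88), Ifi27l2a (2.47), Rsad2 (2.42), Slfn5 (2.01) and Lars2 (1.35) were highest, and Pbx3, Col19a1 (-3.21), Chil3 (-2.04), Tfrc (-2.28) and Aff2 (-1.42) lowest. The ratio was 1.63 for Ifi27l2a with doublets kept, 0.71 for Lars2 with the strict cell filter and -0.28 for Aff2 with equal weight per cell. In monocyte-like cells Xlr4a (log2 5.76, 4.51 to 7.39), Xlr3b (5.82), Xlr3a (at least 19.7-fold over wild type), Ifit3b (4.48) and Ifit3 were highest, and Saa3 (-6.15, -7.07 to -5.37), Cd38 (-6.32), Serpinb9g (-5.93), Pla2g7 (-4.78) and Xlr (-5.23) lowest. Median-of-ratios scaling would add 0.06 to the log2 ratios of immature and 0.12 to those of mature neutrophil-like cells.

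Heterozygous against wild type in stem and progenitor-like cells, dissociation and immediate early genes and NF-kB and inflammatory cytokine genes stood out. All 18 dissociation and immediate early genes were higher in the heterozygous library (median log2 ratio 1.23, 1.17 to 1.31), with the AP-1 gene Fos at 428 and 1802 CPM (log2 2.08, 2.03 to 2.12) and Egr1 at 56.4 and 221 CPM (log2 1.97, 1.84 to 2.10). NF-kB and inflammatory cytokine genes were higher in 22 of 23 members (median 0.77, 0.72 to 0.93), among them the chemokine gene Cxcl2 (53.6 and 241 CPM, log2 2.17) and the NF-kB inhibitor Nfkbia (log2 0.74). MHC class II presentation genes were higher in 12 of 12 (median 0.54, 0.41 to 0.76), with Cd74 at 16.0 and 40.5 CPM (log2 1.34) and H2-Aa higher by log2 2.01 (1.45 to 2.58). In the same library conventional dendritic cell-like cells, whose leading genes were H2-Aa and Cd74 among others, were 4.77% against 1.85% of cells, and Cd74 stood at 476 CPM over all kept cells against 137 CPM in wild type. Secondary and tertiary granule genes were higher in 14 of 16 (median 1.13, 0.97 to 1.29), with Ltf at 8.12 and 59.4 CPM (log2 2.87) and Ngp at 97.3 and 449 CPM (log2 2.21), in a library where 70.2% of cells were granulocytic and Ltf stood at 722 CPM over all kept cells against 141 CPM in wild type. With doublets kept, the log2 ratio was 2.02 for Ltf and 1.55 for Ngp. Primary granule genes were higher in 9 of 10 (median 0.38, percentile 99.99).

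Some lists were lower in the heterozygous stem and progenitor-like cells. They were MYC targets in 24 of 27 members (median -0.30, -0.35 to -0.23, percentile 0.00), ribosomal protein genes in 31 of 31 (-0.13, percentile 0.19), mitochondrially encoded genes in 10 of 13 (-0.35, percentile 0.00), and G2 and M phase genes in 33 of 50 (-0.14, percentile 0.43). Oxidative phosphorylation genes were lower in 26 of 30 members, at a percentile of 2.53 (-0.11). The lists closest to the question of the series lay near 0, with medians of 0.04 (-0.18 to 0.20) for fatty acid binding and uptake, -0.06 for fatty acid oxidation, 0.06 for fatty acid and triglyceride synthesis, -0.11 for cholesterol synthesis, -0.05 for PPAR gamma targets, 0.07 (-0.15 to 0.18) for haematopoietic stem cell genes and -0.05 (percentile 28.1) for the Hox-Meis program. Within the Hox-Meis list Hoxa9 stood at 203 and 132 CPM (log2 -0.62), Meis1 at 1461 and 932 CPM (log2 -0.65) and Pbx3 at 1842 and 1261 CPM (log2 -0.55). Interferon response genes had a median of -0.10 (14 of 33 higher), S phase 0.01, p53 targets -0.10, unfolded protein response -0.09, glycolysis -0.08, hypoxia -0.03, STAT3 and PI3K-AKT feedback 0.05, DNA methylation machinery 0.02, ferroptosis and antioxidant genes 0.03 and haemoglobin RNA 0.03. The sex-linked median was 4.35, with Y-linked RNA at 7.84 CPM in wild-type and 237 CPM in heterozygous cells.

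Ranked genes highest in the heterozygous stem and progenitor-like cells were the peptide transporter gene Slc15a2 (0.503 and 42.5 CPM, log2 6.40, 5.33 to 7.73), Cpa3 (log2 4.33, or 2.45 with doublets kept), Auts2 (2.86, 2.71 to 3.01), Fos, Egr3 (2.53), the heat shock gene Hspa1a (2.13), Egr1, Fosb (1.82), Tnip3 (2.23) and H2-Q7 (2.10). The lowest were Raet1d, Mid1 (-5.05), Psma8 (-3.94), Krtcap3 (-3.13), the chromatin organizer gene Satb1 (498 and 135 CPM, log2 -1.88, -1.99 to -1.77), Ddc (-3.35), Raet1e (-2.01), the lymphoid transcription factor gene Ikzf2 (-1.62, -1.69 to -1.55), Abcc8 (-2.81) and P2ry14 (-1.68). With the strict cell filter the Mid1 ratio was -2.18.

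In the more mature heterozygous classes, dissociation and immediate early genes had medians of 0.73 in granulocyte-monocyte progenitor-like, 0.98 in immature neutrophil-like, 0.62 in mature neutrophil-like and 0.84 in monocyte-like cells, and NF-kB and inflammatory cytokine genes 0.54, 0.72, 0.40 and 0.54. MYC targets had medians of -0.68, -0.52, -0.36 and -0.25 in the same order. Monocyte-like cells had higher PPAR gamma targets (0.38, 0.15 to 0.48, 10 of 15 higher) and MHC class II presentation genes (0.51, 12 of 12). Of these cells, cluster 3 held 33.2% in the wild-type and 23.7% in the heterozygous library, cluster 7 held 24.8% and 6.36%, and cluster 11 held 19.4% and 50.1%. The summed interferon response genes of heterozygous monocyte-like cells were 1.07 times the wild-type level. Conventional dendritic cell-like cells, with MHC class II genes in the lead, were 4.77% of heterozygous and 1.85% of wild-type cells. The Mpo-rich cluster numbered 9 held 23.6% of wild-type and 0.901% of heterozygous granulocyte-monocyte progenitor-like cells, and the primary granule median in that class was -0.49.

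Homozygous against heterozygous, stem and progenitor-like cells had higher interferon response (28 of 30 members, median 0.86, 0.63 to 0.98), ribosomal protein (0.26, 29 of 31), oxidative phosphorylation (0.27, 29 of 30), MYC target (0.33, 24 of 27) and S phase genes (0.37, 36 of 42) in the homozygous library. Dissociation and immediate early genes (median -0.86, 0 of 18 higher), secondary and tertiary granule genes (-0.88, 0 of 16) and MHC class II presentation genes (-0.60, 1 of 12) were lower. Fatty acid and triglyceride synthesis genes had a median of -0.24 (-0.46 to -0.08, percentile 0.20) and fatty acid binding and uptake genes 0.02 (-0.20 to 0.25, percentile 43.2).

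Sex-linked RNA differed between the libraries, and each library held both cells with Xist only and cells with Y-linked RNA only. Xist, transcribed from the inactive X chromosome of female cells, stood at 1270 CPM in wild-type, 207 in heterozygous and 1221 in homozygous kept cells, and 4 Y-linked genes summed to 9.34, 262 and 19.5 CPM. Cells with Xist and no Y-linked UMI were 91.7% of wild-type, 14.6% of heterozygous and 84.0% of homozygous cells, and cells with Y-linked UMIs and no Xist 1.33%, 56.8% and 3.32%. T cell-like cells had Y-linked RNA in each library, at 403, 330 and 355 CPM.

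**Figure D3:**
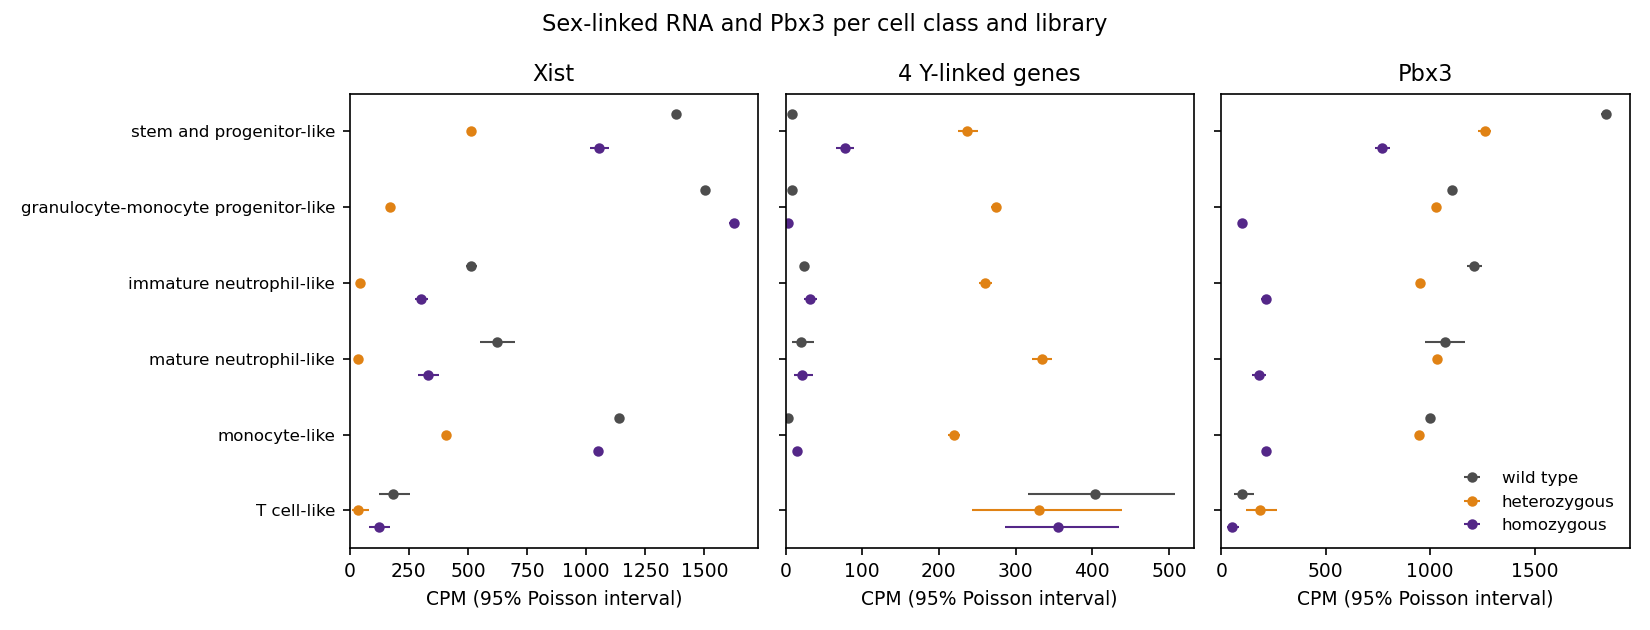
CPM (x axis, with 95% Poisson intervals as bars) of Xist, of 4 summed Y-linked genes and of Pbx3 per cell class in the wild-type, heterozygous and homozygous libraries. Y-linked RNA was low in wild-type granulocyte-monocyte progenitor-like cells (8.06 CPM) and high in wild-type T cell-like cells (403 CPM), and Pbx3 stood at 1106 CPM in wild-type and 98.2 CPM in homozygous granulocyte-monocyte progenitor-like cells.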

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

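The level in barcodes left out by the mitochondrial filter was chosen after the data had been seen, and the level over all barcodes was planned. Barcodes with a mitochondrial share of 10% or more, which enter no comparison of kept cells, also carried Fabp4 RNA. Among them only the wild-type interval lay apart from the homozygous one. Fabp4 stood there at 2.29 CPM in the wild-type library (23 UMIs, interval 1.45 to 3.44), 0.902 CPM in the heterozygous library (5 UMIs, 0.293 to 2.10) and 0.248 CPM in the homozygous library (2 UMIs, 0.0300 to 0.896). The wild-type level was above that of the kept wild-type cells (0.789 CPM), so the filter removed Fabp4 RNA from the wild-type library more than in proportion to its UMIs. That removed wild-type level rests on 11 barcodes with a Fabp4 UMI. Over all barcodes the log2 ratio to wild type was -2.87 (-4.24 to -1.76) for the homozygous and -0.79 (-1.37 to -0.22) for the heterozygous library. The heterozygous interval excluded 0, but it treats UMIs as independent, and they lay in 44 wild-type and 31 heterozygous barcodes. The shares of such barcodes had overlapping intervals, at 0.467% (0.339% to 0.626%) and 0.289% (0.197% to 0.410%). The direction of the heterozygous difference may also depend on cluster make-up. At the wild-type level of each cluster, kept heterozygous cells would have held 21.2 UMIs where 35 were counted (24.4 to 48.7).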

How the results depend on the processing

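No paired analysis was possible because the libraries share only the replicate number 1 and each genotype has 1 library. Alternatives with a mitochondrial limit of 25%, with only kept cells of at least 5000 UMIs and without unnamed clusters (at 10% and at 25%) were added after the data were seen. The Fabp4 ratio to wild type stayed within its interval, from -3.80 to -2.78 (homozygous) and -1.23 to -0.51 (heterozygous). The stem and progenitor-like share was lower in both knockout libraries under each alternative. For homozygous minus wild type (-17.0 points) it was -18.6 with the strict filter, -20.2 with doublets kept, -23.4 at resolution 0.5, -24.6 at 2.0, -21.2 with 15 components, -10.2 by marker score and -19.4 at 25% among named cells. For heterozygous minus wild type (-15.1) the same settings gave -17.0, -17.8, -22.6, -21.1, -19.0 and -10.6, the 25% limit -13.2 and its named cells -17.4. A reversal here is a change of sign in a value whose interval excluded 0. Homozygous minus heterozygous reversed to 0.344 by marker score. The granulocytic homozygous minus wild-type difference (-2.47) reversed to 5.28 (strict filter), 0.222 (resolution 2.0), 2.78 (5000 UMIs), 2.86 (without the unnamed cluster) and 1.85 (25%, named cells), and was -10.2 at 25%. The heterozygous one (30.9) was 36.4 (strict filter), 28.7 (resolution 0.5), 27.5 (marker score) and 26.1 (25%). Other reversals were the granulocyte-monocyte progenitor-like share, heterozygous minus wild type, to 0.830 (strict filter) and 0.947 (5000 UMIs). That share was 6.43%, 0.219% and 0.619% at resolution 0.5 and 6.33%, 0.214% and 0.648% with doublets kept, in wild-type, heterozygous and homozygous cells, and 12.9%, 3.98% and 8.94% with 15 components, 16.9%, 8.25% and 19.5% at resolution 2.0 and 21.1%, 10.7% and 22.0% by marker score. The monocyte-like share, homozygous minus wild type (7.12 points), was 0.297 at 25%, 16.8 in its named cells, 13.5 without the unnamed cluster, 14.6 with the strict filter and between 9.16 and 16.7 for the other clusterings, doublets kept and 5000 UMIs. The immature neutrophil-like share, homozygous minus wild type, went to 0.390 (strict filter), 1.64 (doublets kept), 4.83 (resolution 0.5) and 6.36 (25%, named cells), and homozygous minus heterozygous to 0.661 (resolution 0.5). The mature neutrophil-like share, homozygous minus wild type, went to -2.37 (resolution 0.5). Pbx3 in granulocyte-monocyte progenitor-like cells, heterozygous to wild type, reversed to 0.10 (strict filter) and 0.14 (doublets kept). List medians that reversed were haemoglobin RNA in heterozygous immature neutrophil-like cells (-0.11, minimum of 100 UMIs), sex-linked genes in homozygous stem and progenitor-like cells (-0.39, minimum of 100 UMIs), and by list mean, in heterozygous stem and progenitor-like cells, glycolysis (0.0047) and unfolded protein response (0.14). The Hox-Meis median in homozygous stem and progenitor-like cells was -0.18 as a mean. Some medians of stem and progenitor-like cells with intervals spanning 0 also changed sign across the alternatives. Haematopoietic stem cell genes ranged from -0.14 to 0.16 (homozygous) and from -0.13 to 0.10 (heterozygous). Fatty acid binding and uptake genes ranged from -0.14 to 0.07 in the heterozygous library. For all of these the cause was not tested.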

Other observations

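The pooled mouse, male graft, clone and mixed-library tests below, the filter test of granulocytic cells and the filter and depth tests of the heterozygous stem and progenitor-like share were chosen after their results or related values had been seen. Hoxa9 and Meis1, homeobox genes that normal marrow switches off as myeloid cells mature, were high in maturing cells of all 3 libraries. Meis1 stood at 1461 CPM in wild-type stem and progenitor-like, 1167 CPM in granulocyte-monocyte progenitor-like and 802 CPM in monocyte-like cells, against 105 CPM in T cell-like cells. Homozygous cells held Meis1 at 821, 861, 554 and 84.0 CPM, and heterozygous cells at 932, 747, 588 and 49.2 CPM. Hoxa9 stood at 203, 255 and 114 CPM in the same wild-type myeloid classes and at 22.1 CPM in T cell-like cells. In homozygous monocyte-like cells Hoxa9 reached 175 CPM.

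Some genes that stood apart in 1 library differed within it between cells with Y-linked RNA only and cells with Xist only. Slc15a2, the peptide transporter gene, stood at 52.0 CPM in heterozygous cells with Y-linked RNA only and at 24.9 CPM in those with Xist only, against 0.0356 CPM in wild-type cells with Xist only and 0 UMIs in the same homozygous cells. The 58 wild-type cells outside the T cell class with Y-linked RNA only held Slc15a2 at 18.6 CPM (9 UMIs, 8.52 to 35.4), and whether these are cells of the heterozygous library was not tested. Satb1 in heterozygous cells with Y-linked RNA only was 0.147 times its level in those with Xist only among granulocyte-monocyte progenitor-like cells, 0.439 times among monocyte-like cells and 0.833 times, within counting error, among stem and progenitor-like cells, where its ratio to wild type was ranked low. Xlr4a stood at 14.7 CPM in homozygous cells with Xist only and had 0 UMIs in those with Y-linked RNA only.

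The lower share of stem and progenitor-like cells in both knockout libraries is a first pattern for follow-up. Their cluster scored higher for eosinophils than for stem and progenitor cells, as given above, so the pattern need not be one of stem cells. An unequal loss of barcodes to the mitochondrial filter was tested as a cause of the lower share. With the limit at 25% the wild-type share was 7.52 times the homozygous one (4.96 times among the cells named at that limit). It was 3.34 times the heterozygous one (3.04 to 3.68), against 4.90 and 3.41 times at 10%. These ratios met the bounds set against that cause. The 25% limit raised homozygous cells from 4038 to 6905, but those in named clusters only from 3489 to 3543. Heterozygous cells rose from 7773 to 9561, and named ones from 7710 to 7855. Most added barcodes were thus not classed, and those above 25% stayed out, so the test cannot decide. Heterozygous barcodes over the 10% limit held 13 stem and progenitor markers at a median of 1.59 times their levels in kept cells. The range was 0.499 for Ly6a to 5.19 for Sox4, with Cd34 at 1.17 and Meis1 at 0.931. The medians were 1.10 in the wild-type and 1.15 in the homozygous library. Most markers of granulocyte-monocyte progenitors and monocytes also had higher ratios in the heterozygous than in the wild-type library. Among them were Mpo (3.37 against 2.27) and F13a1 (1.67 against 0.752), while Ms4a3 and Cx3cr1 were lower. The rise was thus not particular to stem and progenitor markers. Whether the filter accounts for part of the heterozygous difference stays open. Shallower knockout cells do not account for all of the lower share, since among kept cells of at least 5000 UMIs the ratios were 4.23 and 3.10 (2.79 to 3.45). What stays open is whether 1 of the pooled mice or grafts carries the difference, as the share was 7.58 points lower in heterozygous cells with Y-linked RNA only than in those with Xist only, and 18.1 points higher (11.9 to 25.8) in the corresponding homozygous cells. Unequal Xist detection may shape these sets, as heterozygous Xist stood at 513 CPM in stem and progenitor-like and 35.6 CPM in mature neutrophil-like cells. The share among heterozygous cells with Xist only was 12.8%, also below the 22.3% of wild-type cells with Xist only. With 1 pool per genotype, Fabp4 genotype and mouse cannot be told apart.

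The second pattern is the excess of granulocytic cells in the heterozygous library. Loss of wild-type neutrophils to the mitochondrial filter was tested as its cause. In wild-type barcodes over the limit, 19 neutrophil markers had a median of 0.395 times (quartiles 0.226 to 0.510) their share of non-mitochondrial UMIs in kept cells. For 29 markers of other myeloid classes the median was 0.943. Among monocyte markers, Ms4a6c stood at 0.247, Ms4a4c at 0.287 and Ly6c2 and Ccr2 at 0.361, but F13a1, Fn1, Csf1r, Klf4 and Cx3cr1 at 0.752 to 1.26. Low neutrophil marker RNA can mean few neutrophils or damaged mature cells that lost it, so the test cannot decide. An earlier test at the 25% limit, where the shares were 58.8% and 32.7%, was set aside, as its bound of 2 already lay above the ratio of 1.79 between the heterozygous and wild-type shares at 10%. A male graft within that pool may account for part of the excess, since the granulocytic share among cells with Y-linked RNA only was 1.93 times that among cells with Xist only, at 40.2% against 37.9% in wild-type cells with Xist only. Lower Xist detection in neutrophils may enlarge that ratio (514 CPM in wild-type immature neutrophil-like and 1382 CPM in stem and progenitor-like cells), the 69 wild-type cells with Y-linked RNA only were 50.7% granulocytic, and the genotype stays open as an untested explanation. The sets were not corrected for free RNA, and 10.4% of heterozygous cells held both Xist and Y-linked UMIs.

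The third pattern is Y-linked RNA in 118 homozygous cells outside the T cell class. Normal host cells beside an Xist-expressing leukaemia were tested by Meis1. The 118 cells held it at 1.13 times (1.05 to 1.21) the level of homozygous cells with Xist only. That value mixes classes, as 21.6% of homozygous cells with Y-linked RNA only were stem and progenitor-like, against 3.57% with Xist only. Meis1 was 1.76 times (1.57 to 1.97) in stem and progenitor-like cells, which may hold it in normal marrow. In monocyte-like cells it was 0.753 times (0.648 to 0.871). Hoxa9 stood at 0.665 times (0.571 to 0.770) in the 118 cells. The monocyte-like Meis1 value argues against host cells in that class only. Cells of the heterozygous library are argued against as well, since the upper bound of Slc15a2 was 0.0725 times the level in that library's cells with Y-linked RNA only. A second leukaemia clone in the pool was tested by Pbx3, which was 14.9 times higher in these cells (14.1 to 15.7). By class it was 7.22 times in stem and progenitor-like, 45.3 in granulocyte-monocyte progenitor-like and 10.4 in monocyte-like cells. But homozygous cells with Xist only were low in Pbx3, as kept wild-type and heterozygous cells held 1243 and 1023 CPM. Cells of any other origin, host cells included, could give a high ratio, so the test cannot tell a clone from them. No label states that the mice carried leukaemia, so a second clone remains a hypothesis.

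As a further hypothesis, interferon in the homozygous marrow may have reached all cells rather than myeloid cells alone. The summed level of 39 interferon response genes in T cell-like cells was 1116 CPM in the wild-type and 1856 CPM in the homozygous library, a ratio of 1.66 (1.41 to 1.97), against 1.72 in monocyte-like, 1.40 in stem and progenitor-like and 1.23 in granulocyte-monocyte progenitor-like cells. The heterozygous T cell-like cells were also higher, at 1.26 times (1.03 to 1.54) wild type, in a library at 0.808 times over all kept cells. The homozygous ratio met the 1.5 set beforehand for the ratio itself, although its lower bound lies under that value. Free RNA of the other cells may raise this ratio in only 24 and 23 T cell-like cells, so the test leaves the hypothesis open.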
